A study of Mus musculus with 5 samples.

How the data were processed

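RNA of sorted tdTomato-positive, lineage-negative cells (lineage-negative is read here as free of the CD31, CD45 and Ter119 stains, which share a colour) was made into libraries with the SMART-Seq v4 low-input kit and read as paired ends on an Illumina instrument. Pregnant females received tamoxifen by mouth for 2 days from E12.5, at 240 mg per kg of body weight. The authors deposited a table of RPKM values (reads per kilobase of gene length, scaled to the library total) for 27179 rows and 5 libraries, per the file headers. The submitters' processing notes name bcl2fastq 2.20.0 and the genome build mm10; the aligner, the counting tool and the annotation are not given in the sources used here. Of the rows, 1306 carry no gene name and were left out of the tests; they held between 2.19% and 3.07% of the summed RPKM of a library. Every column of values was used.

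The column names give the group, a tag (Em2, Em3, Em4, Em8) and digits that resemble a date, but no replicate number, so each column was assigned to its group only. The digits are 210205 for Notch1 cKO Em8 and Notch2 cKO Em3, 210206 for Notch2 cKO Em4 and WT Em4, and 21026 for WT Em2. What they mean is not given in the sources used here. Both WT libraries and Notch1 cKO Em8 carry different digits, so a difference between these groups cannot be told apart from the digits except through the Notch2 cKO pair.

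Whole reads were recovered from the RPKM values. The steps between low values gave the relative depth of the libraries, and the library totals were those at which gene lengths came out as whole bases: 98.3% of 9856 genes did so within a tolerance of 0.02, where 4% would by chance. The recovered reads of a library summed to 99.3% of the total its RPKM values imply. These totals ran from 20740000 to 28830000 reads. The median gene tested had a mean of 738 reads, while 117 genes tested had a mean under 10 reads. A value of 0 allows up to 3 reads, or 1.04 to 1.45 RPKM for a gene of 100 bases, which covers counting error only because the reads carry no molecular identifiers. Of the named genes, 31.7% and 31.3% were listed at 0 in WT Em2 and WT Em4, 26.9% in Notch1 cKO Em8, and 12.7% and 24.5% in Notch2 cKO Em3 and Em4.

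The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(RPKM + 1), with 1 mean per group, all 5 libraries in the fit, and the 11543 genes with a mean of at least 1 RPKM. A fold change is therefore on the log2(RPKM + 1) scale, which understates the change of low genes. The fit left 2 residual degrees of freedom, and the prior fitted across genes added 103.8. The lone Notch1 cKO library was assumed to vary like the other groups. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so every test here borrows its spread across genes. In addition, 29 gene lists were fixed before the data were examined; the 26 with at least 5 genes tested entered camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the same 2 residual degrees of freedom. No list passed with an estimated correlation. The fry test, which asks whether a list's genes move one way on balance and compares them with no other genes, gave adjusted p values of at least 0.55 in all 3 comparisons.

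The genes named in the text followed a rule fixed before the data were examined: 11 Notch and myogenic genes; up to 8 called genes of largest change per direction whose groups do not overlap, without pseudogenes, numbered models and small RNA names of set patterns; for each list past its test the 3 members of smallest p in its direction; and the most abundant member of each list for another cell type or RNA quality. Because many calls rested on few reads, the second part was repeated on genes with a mean of at least 50 reads, a choice made after seeing the data. Positions are those of GENCODE M21 on GRCm38 (the assembly of mm10), matched by symbol, which may not be the annotation the authors used; 24654 of 25873 named genes matched.

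The script was tested on simulated reads for the 11543 genes tested, with 200 genes changed in each of 10 simulations. In Notch2 cKO against WT it recovered 49% of 2-fold and 99.6% of 4-fold changes, and 9.5% of its calls were false. In Notch1 cKO against WT it recovered 21.7% and 93.8%, and 10.4% of its calls were false. The set test called a raised list in 20 of 20 simulations and an unchanged list in 1 of 20. The simulated genes were drawn independently, with the same dispersion of 0.03 for every gene. In the data the correlation estimated per list ran from −0.016 for adipocyte genes to 0.859 for cholesterol synthesis genes, with 0.78 for ribosomal protein genes. The rate of 1 in 20 therefore does not carry over to lists whose genes move together.

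Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 RPKM, 3 other scalings (median of ratios, an equal sum per library, quantile normalization), a variance prior without trend or with robust estimation, only the 2 groups compared, a minimum 1.5-fold change, an estimated correlation, and leaving out each library. The trend of fold change with gene length was removed by a smooth curve over all genes; this was planned for the sarcomere list and added for other lists after their results were seen, with no set test on the corrected values. Added after seeing the data were limma voom on the recovered reads of genes with a mean of at least 10 reads, a mean of at least 50 reads, and the date-like digits as a term, with 21026 read as 210206. The correlation expected with no change was simulated for each set of libraries, with genes drawn independently. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.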

Results

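Transcript levels were measured in tdTomato-positive cells of the muscle progenitor lineage, sorted from the limb muscle of mouse fetuses on embryonic day E16.5. Tamoxifen given from E12.5 activated a CreER recombinase made from the Pax7 locus, which marks the progenitors and their descendants with tdTomato. In the conditional knockout (cKO) groups it also recombined floxed alleles of Notch1 or Notch2, cell-surface receptors whose cleaved intracellular part switches on Hes and Hey repressor genes. There were 2 wild-type (WT) libraries with the recombinase and reporter alone, 1 Notch1 cKO library and 2 Notch2 cKO libraries. Each library is named by its group and the tag in the deposited table. The labels do not say whether the replicates came from separate fetuses or litters, so the p-values do not reach beyond these libraries. Their spread is mostly pooled across genes (2 residual and 103.8 prior degrees of freedom). A gene whose replicates lie far apart can therefore still pass. The read totals that the RPKM values imply were 24420000 for WT Em2, 22860000 for WT Em4, 25550000 for Notch1 cKO Em8, 20740000 for Notch2 cKO Em3 and 28830000 for Notch2 cKO Em4. Across genes, Pearson's r between libraries was 0.984 for the WT pair and 0.976 for the Notch2 cKO pair. With WT Em2 and WT Em4 it was 0.987 and 0.988 for Notch1 cKO Em8, 0.981 and 0.985 for Notch2 cKO Em3, and 0.970 and 0.977 for Notch2 cKO Em4. By this measure Notch2 cKO Em3 lay closer to each WT library than to Notch2 cKO Em4.

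The targeted genes were read first, because they check the labels. Notch1 (ENSMUSG00000026923.15, GRCm38 chromosome 2, 26457903 to 26516663, minus strand) stood at 2.33 RPKM in Notch1 cKO Em8, 7.26 in WT Em2 and 13.5 in WT Em4. It fell by 1.72 on the log2(RPKM + 1) scale in Notch1 cKO against WT (SE 0.39, limma adjusted p = 0.0443), with 565 reads behind the knockout value. Its adjusted p was 0.746 without WT Em4, 0.116 without Notch2 cKO Em3 and 0.12 without Notch2 cKO Em4, and ranged from 0.00036 to 1 over all alternative settings. In the libraries labelled Notch2 cKO, Notch1 was 11.8 and 8.39 RPKM. Notch2 (ENSMUSG00000027878.11, GRCm38 chromosome 3, 98013527 to 98150361, plus strand) stood at 3.35 and 2.03 RPKM in the libraries labelled Notch2 cKO, 2.40 and 4.17 in WT Em2 and WT Em4, and 3.90 in Notch1 cKO Em8. Its log2 fold change in Notch2 cKO against WT was −0.21 (SE 0.32, limma adjusted p = 0.905). Which exons the floxed Notch2 allele loses is not given in the sources used here. A gene-level RPKM pools all exons, so this value checks the Notch2 cKO label in neither direction.

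Hes1, a direct Notch target (ENSMUSG00000022528.8, GRCm38 chromosome 16, 30064384 to 30067796, plus strand), was lowest in Notch1 cKO Em8 at 96.1 RPKM. It stood at 162 and 143 RPKM in Notch2 cKO Em3 and Em4, and at 271 and 194 RPKM in WT Em2 and Em4. These differences did not pass the limma test in Notch1 cKO (log2 fold change −1.25, SE 0.33, adjusted p = 0.16) or in Notch2 cKO (log2 fold change −0.59, SE 0.27, adjusted p = 0.582). Hey1 and Heyl, further Notch targets, did not pass in either knockout. Hey1 was lowest in Notch1 cKO Em8, at 13.7 RPKM against 24.35 and 27.14 in WT, with 18.61 and 30.66 in Notch2 cKO. Heyl stood at 12.82 RPKM in Notch1 cKO Em8, 11.12 and 20.15 in WT, and 12.37 and 15.35 in Notch2 cKO. The fixed list of 23 Notch pathway targets, 18 of them tested, did not pass as a set, with camera adjusted p = 0.567 in Notch2 cKO and 0.488 in Notch1 cKO.

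**Figure D1:**
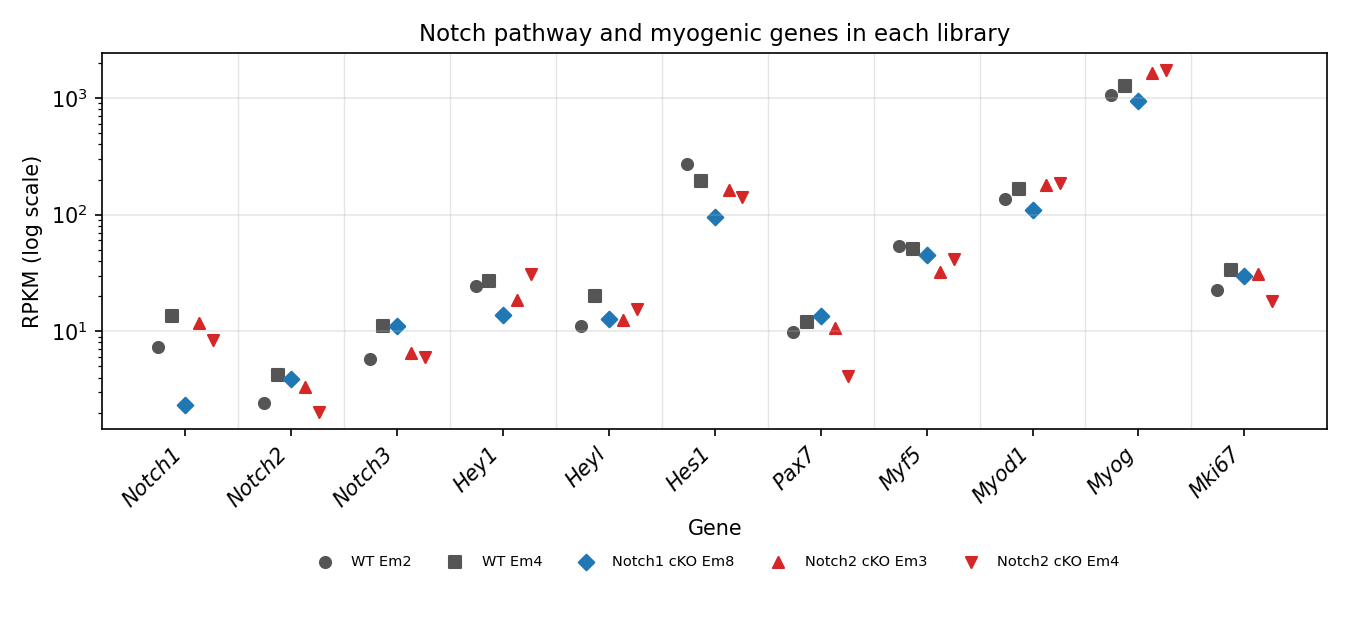
RPKM on a log axis for 11 genes fixed before the data were examined, with 1 point per library and each group in its own colour. Notch1 is lowest in Notch1 cKO Em8 (2.33 RPKM), Hes1 is highest in the WT libraries (271 and 194 RPKM), and Notch2 in the libraries labelled Notch2 cKO (3.35 and 2.03 RPKM) overlaps the WT values (2.40 and 4.17 RPKM).

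The comparison of Notch2 cKO with WT asks what losing Notch2 in the Pax7 lineage changes during fetal myogenesis. Taken as lists, sarcomere genes and genes of myoblast commitment and fusion were higher in the libraries labelled Notch2 cKO, while erythroid and ribosomal protein genes were lower. Mybph, a myosin-binding protein of the thick filament (ENSMUSG00000042451.12, GRCm38 chromosome 1, 134193448 to 134201232, plus strand), rose to 17.5 and 24.3 RPKM from 5.87 and 10.7 RPKM in WT (log2 fold change 1.27, SE 0.31, limma adjusted p = 0.0253). It did not pass without Notch2 cKO Em3 (adjusted p = 0.0674), Notch2 cKO Em4 (0.897) or WT Em2 (1), within a range of 0.00511 to 1 over all alternatives. Of 38 sarcomere genes tested, 33 had a log2 fold change above 0. Of these, 1 passed over all genes and 8 passed adjusted over the list alone. The list's median was 0.38 against 0.14 for all genes, with camera adjusted p = 1e-06 and adjusted p = 0.669 with an estimated correlation. Unc45b, a myosin chaperone, stood at 5.62 and 9.97 RPKM against 2.25 and 3.56 in WT (adjusted p = 0.0975), and the Z-disc protein gene Actn2 at 21.5 and 36.6 against 10.1 and 17.5 RPKM (adjusted p = 0.102).

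In the commitment and fusion list, 28 of 34 genes had a log2 fold change above 0, with a median of 0.35, none past the threshold over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00101, adjusted p = 0.712 with an estimated correlation). Its members of smallest p were Dok7, a gene of the neuromuscular junction (23.1 and 21.4 RPKM against 6.65 and 15.4 in WT), the muscle transcription factor gene Mef2a (34.3 and 31.6 against 19.0 and 16.0 RPKM) and the Notch ligand gene Dll1 (21.1 and 15.8 against 7.71 and 11.5 RPKM). Their adjusted p values were 0.107, 0.185 and 0.285. Myog, the transcription factor of differentiating myoblasts, stood at 1655 and 1737 RPKM in Notch2 cKO and 1053 and 1272 RPKM in WT (adjusted p = 0.734). The progenitor marker Pax7 was 10.7 and 4.15 RPKM against 9.90 and 12.0 in WT (adjusted p = 0.68), and Myf5 was 32.5 and 41.8 against 54.3 and 50.4 RPKM (adjusted p = 0.695). The list of muscle progenitor and quiescence genes did not pass, with a median of 0.21 and 23 of 31 genes tested above 0 (camera adjusted p = 0.428).

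Haemoglobin genes fell in the libraries labelled Notch2 cKO, although the lineage gate of the sort stained the erythroid marker Ter119. Hba-a2 (ENSMUSG00000069917.7, GRCm38 chromosome 11, 32296489 to 32297298, plus strand) stood at 193 and 165 RPKM against 431 and 478 in WT (log2 fold change −1.34, SE 0.28, limma adjusted p = 0.00459). Its near-identical copy Hba-a1 and the beta-globin gene Hbb-b1 fell by 1.16 and 1.11, and reads could be split between such copies. Hba-a2 did not pass without Notch2 cKO Em3 (adjusted p = 0.148) or Em4 (0.691). Hba-a1 and Hbb-b1 did not pass without Notch2 cKO Em3 (0.134 and 0.291), Notch2 cKO Em4 (0.599 and 0.953) or WT Em4 (0.0625 and 0.0601). All 7 erythroid genes tested were below 0, with 3 past the threshold over all genes and 6 adjusted over the list alone (median −1.09, camera adjusted p = 1.78e-16, adjusted p = 0.669 with an estimated correlation). The globin genes named are short, at 563, 559 and 626 bases for Hba-a2, Hba-a1 and Hbb-b1 against a median of 2617 over all genes. Fold changes in this comparison rose with gene length (Spearman's rho 0.248), and the erythroid list was not corrected for this trend.

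Of 44 cytosolic ribosomal protein genes, 3 had a log2 fold change above 0 and none passed on its own, over all genes or adjusted over the list alone. The list's median was −0.60 (camera adjusted p = 1.67e-25, adjusted p = 0.669 with an estimated correlation). The WT libraries also differed in this list: relative to all genes, its median was 0.37 in WT Em2 and −0.37 in WT Em4, against −0.58 and −0.84 in Notch2 cKO Em3 and Em4. Rps3a1, a ribosomal protein gene named by its size of change, fell (SE 0.30, adjusted p = 0.00221) to 367 and 180 RPKM from 777 and 687 in WT, though pseudogene copies can share its reads and its adjusted p was 1 without Notch2 cKO Em4. Nuclear oxidative phosphorylation genes had a median of −0.32 over 42 genes (camera adjusted p = 5.66e-07, adjusted p = 0.708 with an estimated correlation) and replication-dependent histone genes a median of −0.31 over 25 genes (camera adjusted p = 1.35e-09, adjusted p = 0.669 with an estimated correlation). No member of these lists passed over all genes. Without WT Em2, neither list passed (medians −0.053 and −0.006, adjusted p = 0.313 and 0.835). Fold changes also followed gene length, with Spearman's rho of 0.248 across genes in Notch2 cKO against WT and −0.483 for WT Em2 minus WT Em4. Removing this trend took the list medians relative to all genes from −0.445 to 0.035 for histone genes, from −0.459 to −0.126 for oxidative phosphorylation genes and from −0.742 to −0.368 for ribosomal protein genes.

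Stress genes and markers of other cell types were also higher, several of them in a single library. The heat-shock genes Hspa1a and Hspa1b, near-identical neighbours on chromosome 17, stood at 120 and 165 RPKM in Notch2 cKO Em3 but at 4.08 and 6.54 in Notch2 cKO Em4 and at or below 9.23 in the other libraries. The dissociation and immediate early list they belong to had a median of 0.39 over 27 genes, with 2 past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 1.63e-05, adjusted p = 0.669 with an estimated correlation). The list did not pass without Notch2 cKO Em3 (median 0.233, adjusted p = 0.221), nor did Hspa1a and Hspa1b (0.906 and 0.839), which were also lost without WT Em2 (0.803 and 0.55). In the p53 target list, 18 of 19 genes were above 0 (median 0.43, 1 past over all genes and 3 adjusted over the list alone, camera adjusted p = 0.000211, adjusted p = 0.669 with an estimated correlation). Of these, Pmaip1, which encodes the cell-death protein NOXA, rose to 15.6 and 17.6 RPKM from 7.08 and 5.49 in WT (adjusted p = 0.026), and did not pass when a single library of WT or Notch2 cKO was left out (adjusted p = 0.181 without Notch2 cKO Em3, 0.638 without Notch2 cKO Em4, 0.143 without WT Em2, 0.0878 without WT Em4).

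All 15 tendon and cartilage markers tested had log2 fold changes above 0, with a median of 0.88, none past over all genes and 9 adjusted over the list alone (camera adjusted p = 7.15e-08, adjusted p = 0.669 with an estimated correlation). The levels came from Notch2 cKO Em4, where the cartilage matrix gene Matn3 stood at 7.95 RPKM against 0.3 in Notch2 cKO Em3 and 0.2 and 0.65 in WT. Without Notch2 cKO Em4 the list's direction turned, with a median of −0.44 (adjusted p = 2.02e-14), and without WT Em2 the list did not pass (adjusted p = 0.0564). Interstitial fibroblast markers had a median of 0.47 over 17 genes, none past over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000299, adjusted p = 0.669 with an estimated correlation). They did not pass without Notch2 cKO Em4 (median 0.21, adjusted p = 0.181) or without WT Em2 (0.175, adjusted p = 0.123). Adipocyte genes had a median of 0.71 over 7 genes (camera adjusted p = 0.000158, adjusted p = 0.669 with an estimated correlation), with 2 past over all genes and 4 adjusted over the list alone, and did not pass without WT Em4 (adjusted p = 0.0797). The called pair were the brown-fat gene Cidea (4.64 and 4.47 RPKM against 1.65 and 1.01) and the adipokine gene Adipoq (5.36 and 4.59 against 1.70 and 1.35 RPKM). Both calls were lost without Notch2 cKO Em3 (adjusted p = 0.193 and 0.31), Notch2 cKO Em4 (0.262 and 0.222), WT Em2 (0.167 and 0.282) or WT Em4 (0.14 and 0.103).

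In all, 41 genes were higher and 21 lower of 11543 tested, and 881 genes had an unadjusted p under 0.05 where 577 would be expected by chance. Genes that move together can carry this count far from 577 with no change between groups, so the excess counts no changed genes. The median log2 fold change of all genes was 0.14. The split was 41 higher and 40 lower after median-of-ratios scaling (median of all genes −0.05), 28 and 4 after rescaling libraries to the same sum (median 0.30), and 3 and 1 after quantile normalization. Of the 62 calls, 27 had a mean under 50 reads, including Trbd1, a T-cell receptor segment with 1 and 3 reads in Notch2 cKO and 0 in the other libraries. Besides the genes above and the small RNAs AF357359 (higher, log2 fold change 1.32) and Rny3 (lower, −1.01), the genes named by size of change among those with a mean of at least 50 reads were higher Tpsb2, a mast-cell tryptase gene (3.24 and 10.5 RPKM against 0.45 and 2.57), and Arrdc3 (8.31 and 6.13 against 2.09 and 2.71 RPKM). Lower were Shisal2a (6.34 and 6.38 against 23.6 and 15.1 RPKM), Ntn5 (20.3 and 23.7 against 55.4 and 47.4 RPKM) and the transcriptional co-activator gene Cited1 (98.5 and 106 against 220 and 193 RPKM). AF357359 did not pass without Notch2 cKO Em3 (adjusted p = 0.31) or WT Em2 (0.0565). Rny3 did not pass whichever single library was left out (0.0507 without Notch1 cKO Em8, 0.0556 without Notch2 cKO Em3, 1 without Notch2 cKO Em4, 0.599 without WT Em2, 0.115 without WT Em4). Calls were lost without Notch2 cKO Em3 for Arrdc3, Shisal2a, Ntn5 and Cited1 (adjusted p = 0.475, 0.0601, 0.148 and 0.415). Without Notch2 cKO Em4 this held for Tpsb2, Arrdc3, Shisal2a and Cited1 (0.956, 0.197, 0.0768 and 0.537), and without WT Em2 for these 5 genes (1, 0.603, 0.519, 0.437 and 0.437 for Tpsb2, Arrdc3, Shisal2a, Ntn5 and Cited1). Without WT Em2 the test called 7 genes higher and 6 lower, and without WT Em4 52 and 235. Limma voom on the reads recovered from the RPKM values called none, with 1046 genes at an unadjusted p under 0.05. The remaining lists did not pass, with camera adjusted p from 0.0562 to 0.987: Notch receptors and ligands, both cell cycle lists, basal lamina and matrix, BMP and TGF-beta response, unfolded protein and ATF4 stress, interferon response, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded, endothelial, haematopoietic and pericyte genes, besides the Notch target and progenitor lists given above.

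**Figure D2:**
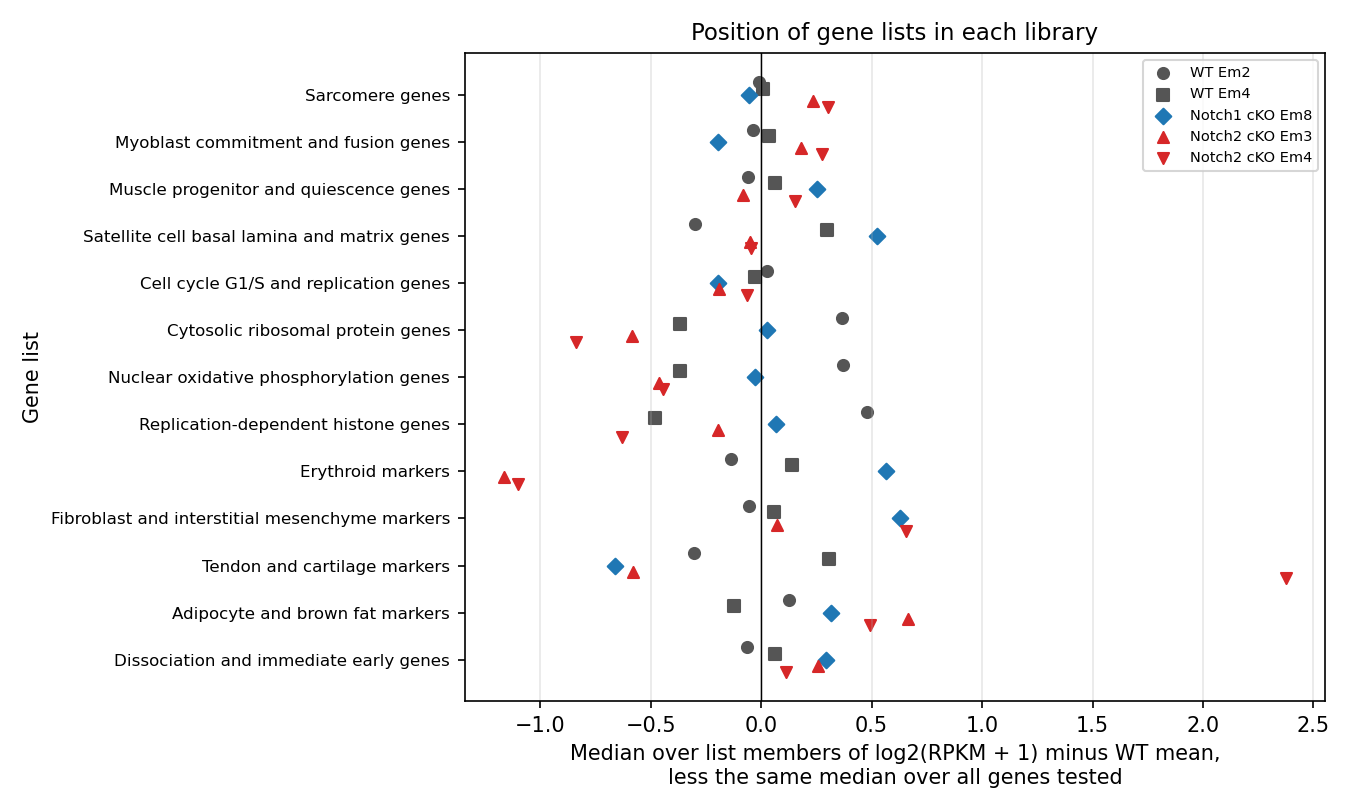
Position of 13 gene lists in each library: the median over list members of log2(RPKM + 1) minus the WT mean, less the same median over all genes tested. Sarcomere genes lie at 0.24 and 0.30 in the libraries labelled Notch2 cKO and at −0.01 and 0.01 in WT, erythroid markers at −1.17 and −1.10 in Notch2 cKO, and tendon and cartilage markers at 2.38 in Notch2 cKO Em4 alone.

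The comparison of Notch1 cKO with WT asks the same question of Notch1, from a single knockout library that is assumed to vary like the other groups. Taken as lists, genes of interstitial fibroblasts, of the extracellular matrix and of the interferon response were higher in Notch1 cKO Em8 than in WT. The interstitial list stood as high in Notch2 cKO Em4: relative to all genes its median was 0.63 in Notch1 cKO Em8 and 0.66 in Notch2 cKO Em4, against 0.07 in Notch2 cKO Em3. Mfap5, a microfibril protein gene of fibroblasts (ENSMUSG00000030116.14, GRCm38 chromosome 6, 122505845 to 122529290, plus strand), rose to 23.4 RPKM from 6.12 and 6.32 in WT (log2 fold change 1.76, SE 0.37, limma adjusted p = 0.0169). Its adjusted p was 0.0519, 0.0517, 0.118 and 0.107 without Notch2 cKO Em3, Notch2 cKO Em4, WT Em2 and WT Em4 in turn. All 17 interstitial fibroblast markers tested had log2 fold changes above 0, with a median of 0.64, 1 past over all genes and 5 adjusted over the list alone (camera adjusted p = 7.47e-23, adjusted p = 0.548 with an estimated correlation). The abundant collagen gene Col3a1 stood at 148 RPKM against 61.7 and 119.6 in WT and 183 in Notch2 cKO Em4, Col1a1 at 25.4 RPKM in both Notch1 cKO Em8 and Notch2 cKO Em4 against 5.23 and 14.8 in WT, and Dpt at 33.6 against 11.7 and 13.2 RPKM.

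All 28 basal lamina and matrix genes were above 0, with a median of 0.53, none past over all genes and 2 adjusted over the list alone (camera adjusted p = 7.79e-21, adjusted p = 0.548 with an estimated correlation). The WT libraries lay apart in this list, at −0.30 in WT Em2 and 0.30 in WT Em4 relative to all genes, and Notch1 cKO Em8 lay above both at 0.52. Dcn, a matrix proteoglycan gene, stood at 75.2 RPKM against 30.7 and 40.7 in WT (adjusted p = 0.424). The interferon list had 13 of 14 genes above 0 and a median of 0.50 (camera adjusted p = 9.74e-08, adjusted p = 0.548 with an estimated correlation), with Ifi27 at 114 RPKM against 59.7 and 58.6 in WT (adjusted p = 0.825). No interferon gene passed over all genes or adjusted over the list alone.

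Progenitor and quiescence genes had a median of 0.26 against 0.009 for all genes, with 24 of 31 above 0 (camera adjusted p = 0.000216, adjusted p = 0.773 with an estimated correlation). Without WT Em2 the list did not pass, and its median of −0.008 against −0.093 for all genes was a smaller shift of the same sign. Commitment and fusion genes had a median of −0.19, with 10 of 34 above 0 (camera adjusted p = 0.00655, adjusted p = 0.797 with an estimated correlation). Without WT Em4 this list did not pass, and its median of 0.023 against 0.1 for all genes was again a smaller shift of the same sign. No gene of either list passed alone. The acetylcholine receptor gene Chrna1 stood at 35.1 RPKM against 54.2 and 54.7 in WT, and Myog at 944 against 1053 and 1272 RPKM (adjusted p = 1 for both). Replication genes of the G1/S list had a median of −0.19, with 5 of 33 above 0 (camera adjusted p = 0.000199, adjusted p = 0.548 with an estimated correlation), as in Rrm2, a subunit gene of ribonucleotide reductase, at 68.9 RPKM against 97.7 and 110 in WT. Sarcomere genes did not pass (median −0.05, camera adjusted p = 0.749).

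Further lists passed with camera: dissociation genes higher (median 0.30, adjusted p = 9.99e-07), mitochondrially encoded genes higher (0.33, adjusted p = 0.00662), pericyte genes higher (0.36, adjusted p = 0.0496), adipocyte genes higher (0.33, adjusted p = 0.0298), G2/M genes lower (−0.09, adjusted p = 0.034) and tendon and cartilage markers lower (−0.65, adjusted p = 0.0296). With an estimated correlation their adjusted p values were 0.552, 0.548, 0.548, 0.548, 0.552 and 0.797 in that order. No member of these 6 lists passed over all genes. The mitochondrial and pericyte lists did not pass without Notch2 cKO Em3 (adjusted p = 0.0822 for both) or Em4 (0.076 for both). Neither did the pericyte list without WT Em2 (median 0.174, adjusted p = 0.401), the G2/M list without WT Em2 (−0.17, 0.0691) or WT Em4 (−0.031, 0.125), and the adipocyte list without WT Em4 (0.169, 0.603). Without WT Em4 the cartilage test pointed up (median −0.155, adjusted p = 0.674). The lists not named here did not pass, with camera adjusted p from 0.0854 to 0.965.

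In all, 5 genes were higher and 3 lower of 11543 tested, and 213 genes had an unadjusted p under 0.05, fewer than the 577 expected by chance. The spread came only from the WT and Notch2 cKO pairs. Across genes, the SD of the log2 difference was 0.41 and 0.443 within these pairs. It was 0.36 and 0.325 between Notch1 cKO Em8 and WT Em2 and Em4. The low count therefore does not show that few genes changed. With the date-like digits as a term, 2 of the 8 calls were kept. Ndufa4l2, a hypoxia-inducible mitochondrial protein gene (ENSMUSG00000040280.10, GRCm38 chromosome 10, 127514967 to 127517154, plus strand), rose to 71.9 RPKM from 15.5 and 18.2 in WT (log2 fold change 2.03, SE 0.35, limma adjusted p = 0.000183). Rarres2, which encodes the chemoattractant chemerin, rose to 35.0 RPKM from 12.1 and 10.4 (adjusted p = 0.0443). Ndufa4l2 did not pass without WT Em2 (adjusted p = 0.0913) or WT Em4 (0.0505). Rarres2 did not pass without Notch2 cKO Em3 (0.0766), Notch2 cKO Em4 (0.0977), WT Em2 (0.193) or WT Em4 (0.383). The other calls besides Notch1 and Mfap5, most of them outside the naming rule and listed after their values were seen, were the small RNA DQ267101 and the pseudogene Ftl1-ps2, both higher, and the small RNAs Snord49a and Mir1898, both lower. When a single WT or Notch2 cKO library was left out, most of the calls of the main test were lost. Without Notch2 cKO Em3, Notch2 cKO Em4 or WT Em2, some of the genes called were not among them. Median-of-ratios scaling gave 13 higher and 9 lower, rescaling to the same sum 2 and 2, and quantile normalization 1 and 0. Limma voom on recovered reads called 1 gene higher.

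The knockouts were also compared with each other, a difference in which the WT means play no part, although the WT libraries still enter the spread. With the WT libraries left out of the fit, 21 genes were higher and 36 lower in place of 32 and 24. Taken as lists, sarcomere genes were higher in the libraries labelled Notch2 cKO than in Notch1 cKO Em8. Erythroid, ribosomal protein, matrix and interferon genes were lower. Fold changes here also rose with gene length (Spearman's rho 0.147), and no list was corrected for this in this comparison. Relative to all genes, WT Em2 and WT Em4 themselves lay at 0.37 and −0.37 in the ribosomal protein list and at −0.30 and 0.30 in the matrix list. Of the sarcomere list, Mybph, the calcium pump gene Atp2a1 and the calcium-binding protein gene Casq2 rose. Atp2a1 (ENSMUSG00000030730.12, GRCm38 chromosome 7, 126445858 to 126463108, minus strand) stood at 19.4 and 33.8 RPKM against 8.65 in Notch1 cKO Em8 (log2 fold change 1.47, SE 0.36, limma adjusted p = 0.0328). In this list 31 of 38 genes were above 0, with a median of 0.44, 3 past over all genes and 6 adjusted over the list alone (camera adjusted p = 4.55e-05, adjusted p = 0.59 with an estimated correlation). Each of these 3 calls was lost without Notch2 cKO Em4 (adjusted p = 0.702 for Mybph and 1 for the others), Casq2 also without Notch2 cKO Em3 (0.0645) and Atp2a1 without WT Em2 (0.0548). Commitment and fusion genes had a median of 0.58, with 28 of 34 above 0, none past over all genes and 6 adjusted over the list alone (camera adjusted p = 9.18e-06, adjusted p = 0.59 with an estimated correlation).

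Hba-a2 fell by 1.91 (SE 0.35, adjusted p = 0.000336) from 676 RPKM in Notch1 cKO Em8, and 4 of 7 erythroid genes fell (list median −1.77, camera adjusted p = 1.07e-11, adjusted p = 0.59 with an estimated correlation). The mast-cell protease genes Cma1, Tpsb2 and Cpa3 rose. Cma1 (ENSMUSG00000022225.7, GRCm38 chromosome 14, 55941451 to 55944675, minus strand) stood at 4.62 and 12.7 RPKM in Notch2 cKO, 0.44 in Notch1 cKO Em8, and 1.52 and 4.55 in WT, with a log2 fold change of 2.61 (SE 0.42, adjusted p = 3.26e-05). Notch1 rose by 1.72 (adjusted p = 0.0148), as the Notch1 cKO label implies, and the non-canonical Notch ligand gene Dner stood at 7.94 and 10.2 RPKM against 2.13 (adjusted p = 0.0207). The immediate early gene Fosb, the interferon-response gene Ifi27, the fibroblast gene Dpt and Crip1 fell, from 61.5, 114, 33.6 and 2072 RPKM in Notch1 cKO Em8 to 21.6 and 19.2, 38.4 and 43.8, 9.76 and 14.9, and 546 and 679 RPKM in the libraries labelled Notch2 cKO. Lost without Notch2 cKO Em3 were Notch1 (adjusted p = 0.241), Dner (0.0777), Ifi27 (0.0777), Dpt (0.363) and Crip1 (0.581). Lost without Notch2 cKO Em4 were Hba-a2 (0.182), Tpsb2 (0.0796), Dner (0.525), Fosb (0.0736), Dpt (0.0574) and Crip1 (0.956), and Dpt was also lost without WT Em2 (0.0575) or WT Em4 (0.0536). Cma1 and Cpa3 passed when any single WT or Notch2 cKO library was left out. The lone Notch1 cKO library could not be left out of this comparison, and with no filter on low values neither gene was called.

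The basal lamina and matrix list had a median of −0.44 (camera adjusted p = 1.79e-07), ribosomal protein genes −0.58 (2.41e-15), oxidative phosphorylation genes −0.33 (0.000157), histone genes −0.33 (7.28e-07), interferon genes −0.45 (0.000625), interstitial fibroblast markers −0.18 (0.00069, with Notch2 cKO Em4 as high as Notch1 cKO Em8 relative to all genes), mitochondrially encoded genes −0.23 (0.0379) and pericyte genes −0.37 (0.0494). G2/M genes had a median of 0.30 (0.0264). With an estimated correlation, adjusted p for these lists lay between 0.59 and 0.601. The fibroblast, oxidative phosphorylation, mitochondrial and pericyte lists did not pass without Notch2 cKO Em3 (adjusted p = 0.178, 0.0948, 0.217 and 0.154). Neither did the mitochondrial and G2/M lists without Notch2 cKO Em4 (0.0548 and 0.0757), and the pericyte list without WT Em2 (0.0811) or WT Em4 (0.0829). Cartilage markers had a median of 1.60 (camera adjusted p = 1.78e-08, adjusted p = 0.59 with an estimated correlation), with 3 of 15 past over all genes, and turned to −0.17 without Notch2 cKO Em4 (adjusted p = 0.00257). The cartilage gene Matn1 stood at 24.2 RPKM in Notch2 cKO Em4, 0.12 in Notch2 cKO Em3 and 0.14 in Notch1 cKO Em8.

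In all, 32 genes were higher and 24 lower, and 1000 genes had an unadjusted p under 0.05 where 577 would be expected by chance. Here too, genes that move together can carry the count far from 577, so the excess counts no changed genes. The split was 47 and 39 after median-of-ratios scaling, 19 and 7 after rescaling to the same sum, and 5 and 8 after quantile normalization, and limma voom on recovered reads called 1 and 7. The lists not named here did not pass, with camera adjusted p from 0.0873 to 0.926.

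**Figure D3:**
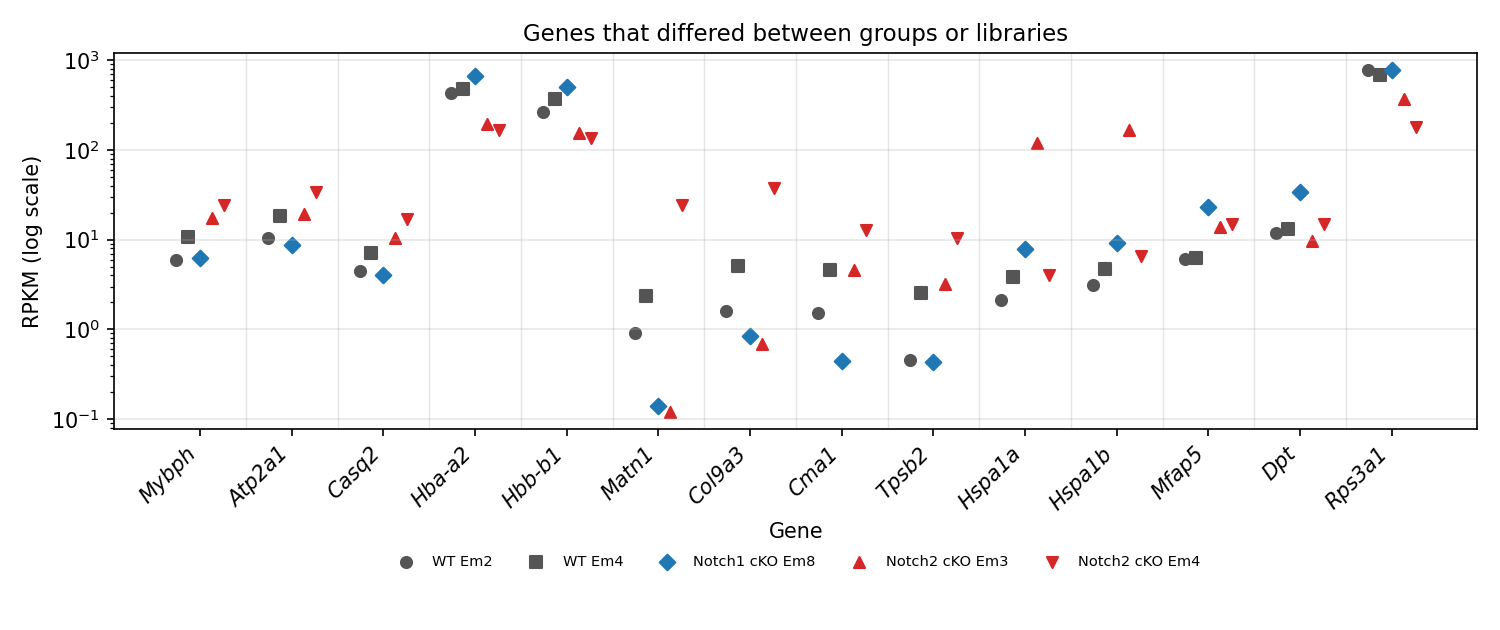
RPKM on a log axis for 14 genes that differed between groups or stood out in a library, with 1 point per library and each group in its own colour. Mybph is highest in the libraries labelled Notch2 cKO (17.5 and 24.3 RPKM), Hba-a2 is lowest there (193 and 165 RPKM), Matn1 stands out in Notch2 cKO Em4 (24.2 RPKM) and Hspa1b in Notch2 cKO Em3 (165 RPKM).

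Both knockouts were set against the same WT libraries, so their fold changes share chance values. Across 11543 genes, Pearson's r of the log2 fold changes was 0.039 and Spearman's rho was −0.024, where genes are not independent replicates. Simulated unchanged knockouts against the same WT libraries gave a mean r of 0.407 (0.383 to 0.428 over 100 simulations). The covariance was 0.004 against 0.045 simulated, a difference of −0.041. The simulated genes were drawn independently, with the same spread of a gene in every library. In the data genes move together, so the narrow simulated range does not show how far 0.039 lies from what no change gives. DQ267101 was the single gene higher in both knockouts, with 22 and 16 reads in Notch2 cKO, 22 in Notch1 cKO Em8 and 3 and 6 in WT, and none was lower in both, where independent lists would share 0.0178 and 0.0055 genes. The DQ267101 call in Notch1 cKO was lost whichever WT or Notch2 cKO library was left out. Its call in Notch2 cKO was lost without Notch2 cKO Em3 or WT Em2. With 2 WT libraries, WT could not be split into separate references of 2 libraries each. The value that no change gives depends on which libraries enter, so it was simulated again in the same way, with independent genes, for each setting. The correlation was −0.05 without Notch2 cKO Em3 and 0.139 without Notch2 cKO Em4 (simulated mean 0.333 for each), and 0.171 without WT Em2 and 0.462 without WT Em4 (simulated mean 0.578 for each). With the date-like digits as a term, an alternative added after seeing the data, the correlation was 0.608 (simulated mean 0.655). Then 16 genes were called the same way in both knockouts. With this term, Notch2 cKO against WT rests on Notch2 cKO Em4 alone. The Notch1 cKO fold change has the difference of Notch2 cKO Em4 minus Em3 added to it. Values of Notch2 cKO Em4 thus enter both fold changes, so these shared calls do not show that both knockouts change alike.

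The Schwann cell and neural list, the keratinocyte list and the sex-linked list had too few expressed genes for a test, with 4 genes each. Their most abundant members were Cnp of the Schwann cell and neural list (8.20 to 13.9 RPKM over the libraries), Krt10 of the keratinocyte list (16.53 to 27.2 RPKM) and Eif2s3y of the sex-linked list (25.6 to 44.2 RPKM). The endothelial gene Egfl7 stood at 33.9 RPKM in Notch1 cKO Em8 and between 15.9 and 19.5 RPKM elsewhere, and the haematopoietic gene Pf4 between 7.87 and 11.5 RPKM in every library. As a list, the 6 haematopoietic genes tested differed between the Notch2 cKO libraries, with medians relative to all genes of 0.86 in Notch2 cKO Em4 and −0.45 in Notch2 cKO Em3, against −0.12 in Notch1 cKO Em8 and −0.05 and 0.05 in WT Em2 and Em4.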

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

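Added after the results were seen were the mean of at least 50 reads, limma voom on recovered reads and the term for the date-like digits; the other alternatives were fixed before. No paired analysis was possible because the columns carry no replicate numbers. For the same reason libraries were left out by their tags, and a group left with 1 library was assumed to vary like the other groups. Set tests were not run with robust estimation, the minimum fold change or voom. Over all alternatives, 3076 fold changes of named genes were recomputed: 2568 kept their direction and side of the threshold, 419 no longer passed, 42 passed newly and 47 reversed. The 2568 include genes that did not pass in the main test and still did not, while only genes called there could be among the 419. Except where fewer genes or libraries were tested, the cause was not tested for any change below.

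With camera, the lists of sarcomere, myoblast commitment, p53 target, ribosomal protein and erythroid genes passed in Notch2 cKO against WT. This held under each alternative run except an estimated correlation. None of these lists passed the fry test, with adjusted p from 0.556 for erythroid genes to 0.615 for commitment and ribosomal protein genes. With an estimated correlation, 0 lists passed in Notch2 cKO against WT, 0 in Notch1 cKO against WT and 0 in Notch2 cKO against Notch1 cKO, in place of 11, 12 and 13. The number of lists past the threshold stayed between 9 and 13, 10 and 13, and 11 and 17 when single libraries were left out.

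Counts of genes are given in the order Notch2 cKO against WT, Notch1 cKO against WT, Notch2 cKO against Notch1 cKO, each as higher and lower, in place of 41 and 21, 5 and 3, 32 and 24. A pseudocount of 0.1 gave 31 and 19, 9 and 6, 24 and 16, and 0.5 gave 35 and 19, 6 and 4, 27 and 20. With no filter limma called 0 and 0, 0 and 0, 0 and 0 among 23440 genes, with 1050, 301 and 983 genes at an unadjusted p under 0.05. A mean of at least 5 RPKM gave 14 and 19, 5 and 2, 24 and 23, and a mean of at least 50 reads 29 and 16, 4 and 1, 42 and 23. Median-of-ratios scaling gave 41 and 40, 13 and 9, 47 and 39. Rescaling to the same sum gave 28 and 4, 2 and 2, 19 and 7. Quantile normalization gave 3 and 1, 1 and 0, 5 and 8. A prior without trend gave 27 and 9, 4 and 3, 15 and 11, and a robust prior 40 and 26, 8 and 5, 38 and 25. The 2 groups alone gave 39 and 20, 5 and 2, 21 and 36. A minimum 1.5-fold change gave 6 and 0, 1 and 1, 2 and 1. The date-like digits as a term gave 43 and 9, 19 and 10, 19 and 12. Of the calls of the main test, 17 of 62, 2 of 8 and 16 of 56 were kept with this term. Limma voom gave 0 and 0, 1 and 0, 1 and 7, with 1046, 199 and 939 genes at an unadjusted p under 0.05.

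Leaving out single libraries gave 7 to 52 genes higher and 6 to 235 lower in Notch2 cKO against WT, 1 to 3 higher and 0 to 2 lower in Notch1 cKO against WT, and 22 to 45 higher and 13 to 42 lower in Notch2 cKO against Notch1 cKO. Of the 62 genes called in Notch2 cKO against WT, 16 were called without Notch2 cKO Em3, 22 without Notch2 cKO Em4, 11 without WT Em2, 37 without WT Em4 and 35 with a mean of at least 50 reads.

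The fall of Notch1 in Notch1 cKO kept its direction and no longer passed at −1.72 with no filter (adjusted p = 1), with the 2 groups alone (0.119) and with a minimum 1.5-fold change (1), at −1.83 after rescaling to the same sum (0.562), −1.79 after quantile normalization (0.0916), −2.17 with the date-like digits (0.34) and −2.09 with limma voom (0.0681). Without single libraries it ran from −2.13 to −1.31.

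Fold changes that reversed were near 0 for the most part. With median-of-ratios scaling these were Notch1 in Notch2 cKO against WT (−0.19) and Heyl in Notch2 cKO against Notch1 cKO (−0.035). After rescaling to the same sum they were Hey1 (0.067) and Heyl (0.048) in Notch2 cKO against WT. After quantile normalization they were Notch1 in Notch2 cKO against WT (−0.18), and Heyl (−0.10) and ND4 (0.045) in Notch2 cKO against Notch1 cKO. With the date-like digits as a term they were, in Notch2 cKO against WT, Notch1 (−0.22), Hey1 (0.25) and Heyl (0.03). In Notch1 cKO against WT they were Notch2 (−0.29), Heyl (0.077), Pax7 (−0.91), Myf5 (0.13), Mki67 (−0.59), Ccne2 (0.10), Kif20a (0.35), Kif2c (0.11), Matn1 (3.32), Col9a3 (3.38) and Snorc (2.83). In Notch2 cKO against Notch1 cKO they were Heyl (−0.047), Mki67 (0.034), Matn1 (−0.021) and Col9a3 (−0.12). By its design this term adds Notch2 cKO Em4 minus Em3 to each fold change of Notch1 cKO against WT.

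Leaving out single libraries moved fold changes across 0 in Notch2 cKO against WT for Notch1 (−0.41 to 0.41), Notch2 (−0.51 to 0.10), Notch3 (−0.74 to 0.10), Hey1 (−0.45 to 0.25), Heyl (−0.52 to 0.29), Mki67 (−0.55 to 0.16), Matn3 (−0.11 to 2.67), Col9a2 (−0.40 to 2.75) and Col9a1 (−0.55 to 2.50). In Notch1 cKO against WT it did so for Notch2 (−0.077 to 0.53), Notch3 (−0.001 to 0.84), Heyl (−0.61 to 0.19), Mki67 (−0.14 to 0.40) and Fabp4 (−0.19 to 0.85). In Notch2 cKO against Notch1 cKO the ranges were −0.047 to 0.24 for Heyl, −0.68 to 0.034 for Mki67, −0.021 to 4.47 for Matn1 and −0.12 to 4.38 for Col9a3.

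The correlation of the knockout effects was 0.139 with a pseudocount of 0.1, 0.072 with 0.5, 0.092 with no filter, −0.037 with a mean of at least 5 RPKM, 0.071 with median-of-ratios scaling, −0.002 with quantile normalization, −0.014 with a mean of at least 50 reads and 0.608 with the date-like digits. Without single libraries it ran from −0.05 to 0.462. With the date-like digits, values of Notch2 cKO Em4 enter the fold changes of both knockouts. Genes called the same way in both knockouts numbered 5 with a pseudocount of 0.1, 2 with 0.5, 4 with median-of-ratios scaling, 16 with the date-like digits, 0 with no filter, rescaling to the same sum, quantile normalization or a mean of at least 50 reads, and 0 to 1 without single libraries.

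Depth limits the genes with few reads. In Notch2 cKO against WT 17 calls had a mean under 10 reads and 10 a mean of 10 to 50 reads. A single read in a gene of 1 kilobase is 0.035 to 0.048 RPKM.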

Other observations

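The tests of the length trend in sarcomere genes, of fewer progenitors and of counting noise were chosen before their results were seen, and the other tests below after the patterns were seen.

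Sarcomere genes were higher in the libraries labelled Notch2 cKO. Against the length trend as the whole cause, removing it left the list 0.431 above all genes (0.240 before), while the same step took histone genes from −0.445 to 0.035, oxidative phosphorylation genes from −0.459 to −0.126 and ribosomal protein genes from −0.742 to −0.368. The list lay 0.235 and 0.302 above all genes in the Notch2 cKO libraries, against −0.01 and 0.01 in WT. The set test already compares the list with all other genes. These positions therefore restate the pattern and add no separate evidence against a shift of all genes. Fewer progenitors among the sorted cells could raise the share of differentiating cells, and the progenitor list, at −0.08 in Notch2 cKO Em3 and 0.155 in Notch2 cKO Em4 relative to all genes, leaves that open. Earlier differentiation after Notch2 loss was not tested.

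Interstitial mesenchyme genes were higher in the Notch1 cKO library than in WT, and as high in Notch2 cKO Em4 (0.63 and 0.66 relative to all genes). Low values in WT Em2 alone are argued against, since the list stayed 0.438 above all genes against WT Em4. Interstitial cells could raise these markers although the sort was gated for tdTomato-positive cells of the Pax7 lineage, and their share was not measured. That 17 of 17 lay above the median of all genes restates the pattern and decides nothing. A day shared with Notch2 cKO Em3 stays open too, since its −0.57 relative to Notch2 cKO Em4 compares single libraries, and Notch2 cKO Em4 stands apart in tendon and cartilage markers (2.38). With 1 Notch1 cKO library, an effect of Notch1 loss on these genes was not told apart from the make-up of that sort.

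Among genes with a mean under 10 reads, 17 of 117 tested were called between Notch2 cKO and WT. Counting noise could give as many: 2 of 20 simulations of unchanged libraries had at least 17 such calls (mean 6.75, 0 to 22). Among genes with 10 reads or more the simulations gave at most 4 calls where 45 were observed. The simulated genes were drawn independently with the same dispersion of 0.03, which was set and not fitted to the libraries. The simulations therefore do not show that the 45 calls exceed the real spread between libraries. Background reads in the Notch2 cKO libraries could also raise such genes, and 82.4% of these calls were higher in Notch2 cKO, 9 of 14 of them higher in Notch2 cKO Em3 than in Notch2 cKO Em4. By the reads of sensory receptor genes scaled to library totals, Notch2 cKO Em3 alone stood above Notch1 cKO Em8. Both explanations stay open, and no biological explanation was tested.

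Of 1478 genes for olfactory and vomeronasal receptors, 49.3% had at least 1 read in Notch2 cKO Em3, 17.9% in Notch2 cKO Em4, 11.2% in Notch1 cKO Em8, 3.5% in WT Em2 and 3.9% in WT Em4. Scaled to library totals as CPM, the reads of these genes came to 83.9, 21.1, 22.1, 9.58 and 13.3 in that order, so that Notch2 cKO Em4 was not above Notch1 cKO Em8.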
